A study of Drosophila melanogaster with 8 samples.

How the data were processed

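Small RNAs of 18 to 29 nt were isolated from ovaries of Drosophila melanogaster females aged 5 to 6 days and grown at 25 °C, and were cloned and sequenced, per the labels' protocols. There were 8 libraries, 1 per genotype. A heterozygous and a mutant library were made for each of armi, CG4771, fs(1)Yb (written Yb below) and zuc.

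The authors deposited one table for the whole series. It lists each distinct sequence, the number of genome positions at which it was found and, as whole-number counts in columns whose names end in mult, its copies in each library, per the file headers and the values. The aligner, the mismatches allowed and the genome build are not given in the sources used here. The table held 24231972 sequences, of which 13700630 had a read in at least 1 of the 8 libraries. Columns were matched to libraries by name. A pair of columns carried the prefix "avo" and the allele name delta1. These were taken as the CG4771 pair because delta1 is in the titles of that pair alone and the other columns name the other genes. The match is by elimination, since "avo" itself is in no label and the armi genotype per the labels also carries the word delta1.

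The deposited table holds no genome coordinates and no genome sequence was used here. The flamenco and 42AB clusters, the 3' UTR of traffic jam and the named transposon families, which had been chosen before the data were examined, were therefore not analysed here, and neither was the expression of the mutated genes themselves. Reads were instead joined to one another. A greedy assembly with words of 18 nt, started from words seen at least 5 times and keeping contigs of at least 40 nt, was written in C++ (g++ 11.4.0), and reads were placed on the contigs by exact match. Contigs can be fusions of separate genomic stretches, and the contig of 10483 nt was seen to join 28S rRNA to other sequence.

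The miRNAs were recognised by their first 19 nt against 64 mature sequences written from general knowledge, not taken from a database. Each of the 64 occurred in the reads at full length. The list is not complete, so the normalizer is the sum over listed miRNAs, and reads described as outside the list include any miRNA not on it. Reads over 26 nt were not counted as miRNA. The 2S, 18S, 28S, 5S and 5.8S rRNAs, U2 and U6 snRNA and the hairpin endo-siRNA esi-2.1 were likewise recognised by hand-written sequences or motifs.

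A piRNA-length read had 23 to 29 nt, was no listed miRNA and lay outside masked sequence. Only reads placed on a contig could be masked, so reads placed on none were kept unscreened in the levels. Placed reads were 81.8% to 82.3% of piRNA-length reads in the heterozygotes and 70.9% to 80.4% in the mutants. They were fewest in zuc (70.9%) and armi (71.1%). The levels of the mutants therefore hold a larger unscreened share. Locus values and ping-pong shares used placed reads only. Masked sequence was set on the pooled heterozygotes, each weighted equally. Tiles of 100 nt with at least 100 reads were masked when at least 97% of reads lay on 1 strand and either the reads of 18 to 22 nt came to at least 10% of those of 23 to 29 nt or under 35% of reads began with U. Contigs under 250 nt with a tRNA B box were masked too. After the first results had been seen, 28S rRNA fragments were found to remain in the piRNA-length set of the armi mutant. Contigs carrying an rRNA or snRNA motif were then masked whole if under 250 nt, and on longer ones gaps of up to 5 tiles between masked tiles were filled. This changed the armi level from 77.9% to 38.7% of the heterozygote, and both values are given. The mask, the assembly and the strand classes were all chosen after the data had been examined.

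Levels were reads per miRNA read of the same library, as fixed before the data were examined. Mutant to heterozygote ratios carry 95% Clopper-Pearson intervals with the normalizer taken as fixed, and shares of reads carry 95% Wilson intervals. Copies of a sequence carry no molecular identifiers, so these intervals cover counting error only. With 1 library per genotype no test of a single mutant against its heterozygote was possible. An effect shared by the mutants of all 4 genes was not tested, since each gene was compared by itself, as fixed before the data were examined. For each gene the range over the 4 heterozygotes is shown as a yardstick although these differ in genotype. A ratio was called lower or higher when it was under 0.5 or over 2 and the mutant lay outside the range of the 4 heterozygotes.

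Ping-pong share was the percentage of opposite-strand read pairs with a 5' overlap of 10 nt among overlaps of 1 to 20 nt, with reads divided by their number of genome positions. Its interval came from 1000 resamplings of 2000 nt blocks of contigs and covers the sampling of loci only. The mutant and the heterozygote were resampled separately. The interval of a difference therefore ignores that both libraries share loci. Loci were contigs of at least 200 nt with at least 1000 piRNA-length reads over the 4 heterozygotes. They were called uni-strand when at least 95% of reads in the pooled heterozygotes lay on 1 strand and dual-strand when under 90% did. A count of 0 in a mutant was set to 0.5 reads for ratios, and medians were repeated with such loci at a floor of 3 reads. Class medians carry 95% order-statistic intervals over loci, which are not replicates, and were set against 10000 random lists of loci matched on heterozygote abundance. The gap between class medians carries a 95% interval from 1000 resamplings of loci.

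The miRNAs named were, for each comparison, the 4 with the highest and the 4 with the lowest ratio among those with at least 1000 reads in the mutant or the heterozygote. Fixed miRNA lists (the mir-309 and mir-310 clusters, ovary-enriched miRNAs, the let-7 complex, and miRNAs of muscle and neurons) were described by their counts and by the percentile of their median among 10000 random lists matched on abundance. The loci named were the 5 of each class with the most reads in the heterozygotes, a rule set after the data were seen and without use of the ratios.

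The procedures were tested on simulated data. From 200 simulated loci of random sequence 200 contigs were assembled, each an exact stretch of a simulated locus. Repeated sequence was not simulated, so the fusing of separate stretches was not tested. In the simulated armi comparison a fold of 0.25 at 50 loci was recovered as 0.251, and in the simulated zuc comparison a fold of 0.05 at 50 loci was recovered as 0.0503. No fold below 0.05 and no mutant counts near 0 were simulated. Recovery of lower medians, such as those of uni-strand loci in armi and zuc, was therefore not tested. Among 4000 simulated pairs the ping-pong share came to 52.6% against a true 52.6%. These pairs were isolated from one another, so this checks the calculation only and not overlapping reads or repeats. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

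Alternatives fixed before the data were examined were normalization to all mapped reads, a window of 24 to 28 nt, genome-unique reads and, for the ping-pong share, counting each distinct sequence once. Normalization to annotated hairpin endo-siRNA loci needed coordinates and was not run. The alternatives of esi-2.1 as normalizer, U-initial reads, tiles of 200 nt as loci, reads of 18 to 22 nt and esi-2.1 per mapped read, reads summed over a class, counts under 3 set to 3 for the gap between classes, the miRNA lists per mapped read and the mask without its later addition were added after the data had been seen.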

Results

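Small RNA libraries from ovaries of armi, CG4771, Yb and zuc mutants were compared with libraries from the matching heterozygotes, to ask how loss of each gene changes ovarian piRNAs. piRNAs are small RNAs of the germline and its supporting somatic cells that silence transposons. Armi is a putative RNA helicase, Zuc a nuclease of the phospholipase D family, Yb a Tudor-domain protein of the ovarian soma, and CG4771, listed as vret in the reference gene table, encodes a Tudor-domain protein. The libraries held 17373814 to 28132377 mapped reads, the fewest in the CG4771 mutant. The 4 heterozygotes held 25278388 to 28132377. There was 1 library per genotype, so no difference below has a replicate check, and each describes the libraries and not the genotypes in general.

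In the heterozygotes, piRNA-length reads made up 59.6% to 68.7% of each library and listed miRNAs 17.9% to 26.1%. Of the piRNA-length reads, 73.0% to 76.3% began with U and 32.5% to 37.5% had A at the tenth base. Between 2.28 and 3.79 piRNA-length reads were sequenced per miRNA read, a 1.66-fold spread among the heterozygotes.

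**Figure D1:**
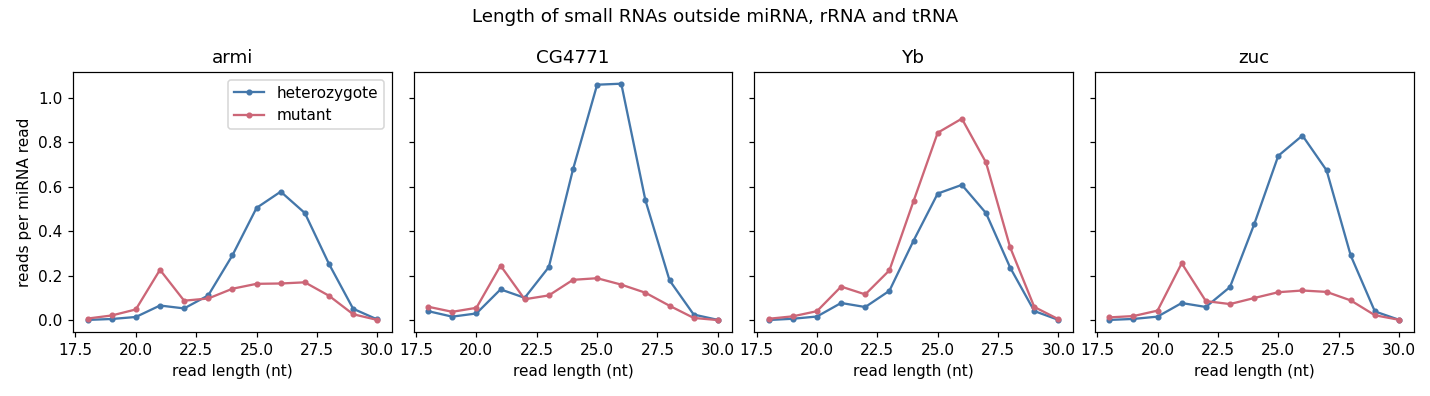
Reads per miRNA read (vertical axis) by read length in nt (horizontal axis) in each heterozygote (blue) and mutant (red), outside listed miRNAs and masked rRNA and tRNA sequence. Lines join the values of 1 library each. The broad peak of 24 to 28 nt is lower in the armi, CG4771 and zuc mutants than in their heterozygotes, and the Yb mutant lies above its heterozygote on this scale.

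In the zuc mutant, piRNA-length reads fell to 21.4% of the heterozygote (95% interval 21.4 to 21.4), from 3.16 to 0.677 per miRNA read, below all 4 heterozygotes. Of the remaining reads, 68.7% began with U (95% interval 68.7 to 68.8), against 76.3% in the heterozygote, and 45.3% had A at the tenth base, against 32.5%. Of 180 uni-strand loci 175 were lower, 1 was higher and 4 were neither, with a median of 1.98% of the heterozygote (95% interval 1.82 to 2.21). Of 783 dual-strand loci 735 were lower, 6 were higher and 42 were neither, with a median of 2.80% (95% interval 2.60 to 3.09). Of these 783 loci, 540 were read mostly from repeated sequence and 64 mostly from 1 genome position. Their medians were 3.11% and 2.87%. A contig of repeated sequence can merge copies, so its strand share need not be that of any 1 genomic locus. The upper quartile of the dual-strand loci was 9.46%. The most abundant loci kept more. The 5 most abundant uni-strand loci, contigs of 4985, 2249, 2132, 1193 and 1024 nt, stood at 9.86%, 4.53%, 3.22%, 13.1% and 17.02%. The 5 most abundant dual-strand loci, contigs of 10136, 5426, 10483, 3186 and 8603 nt, stood at 26.02%, 19.8%, 9.50%, 51.4% and 23.7%. The contig of 10483 nt, the third of these in every comparison, is a fusion that also carries 28S rRNA. Its masked rRNA stretch is left out of these values, but its place as a single piRNA locus is uncertain. Summed over their class, reads stood at 6.98% for uni-strand and 21.1% for dual-strand loci.

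In the armi mutant, piRNA-length reads stood at 38.7% of the heterozygote (95% interval 38.6 to 38.7), at 0.881 per miRNA read against 2.28. Normalized to all mapped reads the value was 14.6%, and it was 77.9% before residual 28S rRNA fragments were masked. Masked sequence held 84.8% of all reads of 23 to 29 nt in the armi mutant. It held 61.7% in the zuc mutant, 30.03% in Yb and 29.99% in CG4771, against 6.53% to 10.6% in the heterozygotes. The armi level is thus a small remainder after masking. Incomplete masking could move it far beyond its counting interval. The share beginning with U was 65.5% against 74.9% in the heterozygote, and that with A at the tenth base 45.4% against 35.8%. Among uni-strand loci 176 were lower, 0 were higher and 4 were neither, with a median of 1.49% (95% interval 1.23 to 1.94). At 22 of these loci no read was counted in the mutant, and with those at a floor of 3 reads the median was 2.08%. Of the dual-strand loci 686 were lower, 7 were higher and 90 were neither, with a median of 5.32% (95% interval 4.77 to 5.98) and an upper quartile of 22.7%. The same 5 dual-strand contigs, in the same order, stood at 40.5%, 90.6%, 14.02% (the 28S rRNA fusion), 122.2% and 23.2%, and the same 5 uni-strand contigs at 15.1%, 6.03%, 4.61%, 28.9% and 8.98%. Reads summed over a class stood at 10.8% for uni-strand and 37.03% for dual-strand loci.

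In the CG4771 mutant, piRNA-length reads fell to 22.4% of the heterozygote (95% interval 22.3 to 22.4), from 3.79 to 0.847 per miRNA read. Normalized to all mapped reads the value was 40.02%. The share beginning with U was 55.8%, against 73.0%. Uni-strand loci had a median of 5.25% (95% interval 4.98 to 5.71), with 166 lower, 0 higher and 14 neither. Dual-strand loci had a median of 7.30% (95% interval 6.68 to 8.33), with 713 lower, 8 higher and 62 neither. The 5 dual-strand contigs stood at 38.1%, 25.3%, 16.9% (the 28S rRNA fusion), 58.1% and 35.4%, and the 5 uni-strand contigs at 24.6%, 9.54%, 8.47%, 21.1% and 8.49%. Reads summed over a class stood at 12.8% for uni-strand and 23.2% for dual-strand loci. Reads of 18 nt made up 5.29% of this library and 1.83% of its heterozygote, against 0.0901% to 0.126% in the other heterozygotes, so the CG4771 pair differed from the rest in the lengths it held.

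In the Yb mutant the locus classes lay on either side of the heterozygote, per miRNA read. Dual-strand loci had a median of 163.0% of the heterozygote (95% interval 158.8 to 169.1), with 5 lower, 118 higher and 660 neither. Uni-strand loci had a median of 45.4% (95% interval 38.5 to 54.6), with 97 lower, 4 higher and 79 neither. The 5 uni-strand contigs stood at 98.0%, 139.9%, 63.3%, 91.0% and 54.6%, and the 5 dual-strand contigs at 137.3%, 185.4%, 172.2% (the 28S rRNA fusion), 174.5% and 101.9%. The uni-strand contig of 4985 nt held 40.2% of the class in the heterozygotes, and reads summed over the class stood at 83.5%, so the lower median describes mostly the less abundant loci. Dual-strand loci summed to 153.4%. The medians of one heterozygote over another reached a 3.36-fold difference at uni-strand loci and 1.93-fold at dual-strand loci, so each Yb median taken alone lay within the differences seen between heterozygotes. All piRNA-length reads together stood at 148.4% of the heterozygote (95% interval 148.3 to 148.5), at 3.61 per miRNA read, inside the range of the 4 heterozygotes. This direction depended on the normalizer, since the value was 80.6% per mapped read. Dual-strand loci then had a median of 88.6%, with 52 lower and 10 higher, and uni-strand loci 24.7%, with 131 lower and 2 higher. On that scale heterozygotes differed by up to 2.37-fold at uni-strand and 1.36-fold at dual-strand loci, so the uni-strand median lay beyond their spread and the dual-strand median within it. At the 106 uni-strand loci read mostly from 1 genome position the median was 44.6%, and at the 52 read mostly from repeated sequence it was 46.2%. The miRNA normalizer itself changed in make-up. From heterozygote to Yb mutant, miR-994-5p went from 128806 to 16671 RPM, counted over miRNA reads, and miR-318-3p from 106388 to 50953. In armi they went from 105762 to 11875 and from 128052 to 31078. A fall of such abundant miRNAs makes the normalizer smaller, which raises levels and other miRNA ratios per miRNA read. Levels without these miRNAs were not computed.

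The gap between the classes does not depend on the normalizer and was not particular to Yb. The dual-strand median exceeded the uni-strand median by 1.84 on the log2 scale in Yb (95% interval 1.57 to 2.08) and by 1.84 in armi (95% interval 1.42 to 2.13). In armi the gap was 1.16 with counts under 3 set to 3. It was 0.50 in zuc (95% interval 0.32 to 0.69) and 0.48 in CG4771 (95% interval 0.30 to 0.68). Between heterozygotes it reached 0.80 in size, so the gaps of zuc and CG4771 lay within that spread and those of Yb and armi beyond it. This order rests on medians over loci. By reads summed over a class, uni-strand and dual-strand loci lay further apart as a ratio in zuc (6.98% and 21.1%) than in Yb (83.5% and 153.4%). Such sums were not compared between heterozygotes, so this order has no yardstick. Among 10000 random lists of loci matched on abundance, the uni-strand median was at percentile 0 in armi, Yb and zuc and at percentile 0.16 in CG4771. Such lists take loci as the units, so these percentiles do not show a class difference beyond that between heterozygotes.

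**Figure D2:**
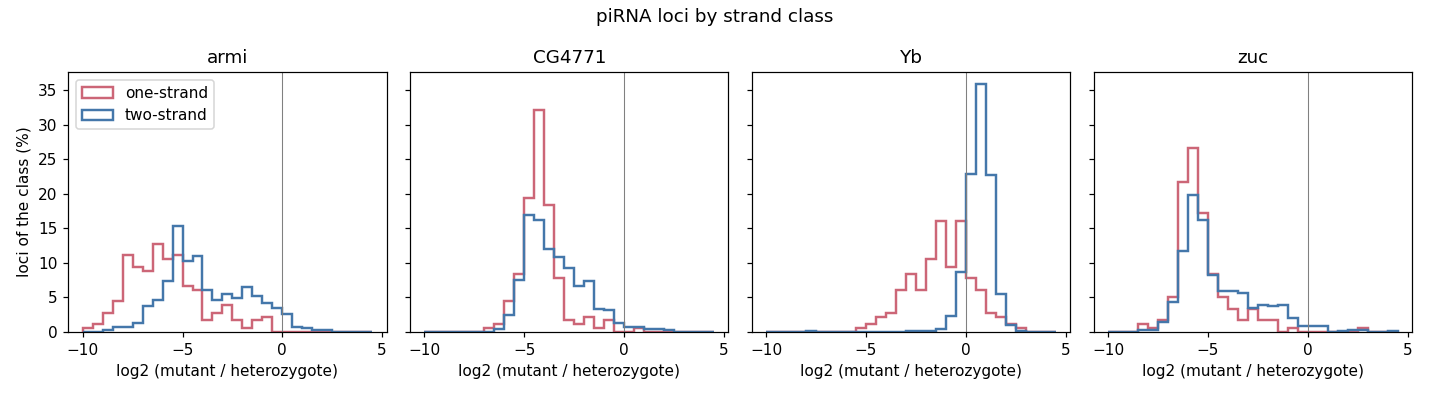
Percentage of loci of a class (vertical axis) by log2 ratio of mutant to heterozygote, per miRNA read (horizontal axis, bins of 0.5), for 180 uni-strand loci (red, labelled one-strand) and 783 dual-strand loci (blue, labelled two-strand). Values beyond the axis are drawn at its end. The classes part in Yb, with medians of 45.4% and 163.0% of the heterozygote, and as far in armi, with 1.49% and 5.32%, where both lie mostly below 0.

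The ping-pong signature, a 10 nt overlap of the 5' ends of reads from opposite strands, was compared as a share of read pairs. In the heterozygotes it was 48.7% for armi, 50.7% for CG4771, 38.7% for Yb and 48.0% for zuc. It was 65.7% in the zuc mutant, higher than in the heterozygote by 17.8 percentage points (95% interval 8.46 to 23.8). A single block of 2000 nt gave 39.4% of the 10 nt pairs of that library, and without the leading block the share was 63.97%. In the armi mutant it was 63.1%, higher by 14.4 points (95% interval 5.74 to 21.9). For CG4771 the difference was 6.75 points (95% interval -3.41 to 17.8) and for Yb -1.48 points (95% interval -8.81 to 5.78), and both intervals included 0. With genome-unique reads the difference was -5.30 points in CG4771 and 34.9 in zuc. With each distinct sequence counted once all shares were lower, at 14.5% in the armi mutant against 6.83% (7.67 points) and at 11.5% in the zuc mutant against 6.64% (4.83 points). The Yb difference was then 0.283 points.

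**Figure D3:**
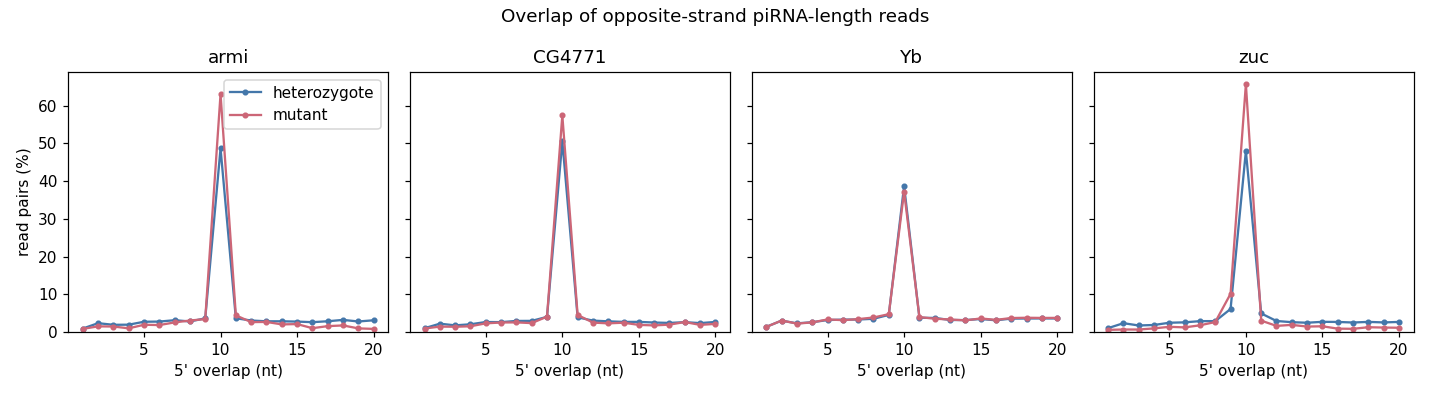
Percentage of opposite-strand pairs of piRNA-length reads (vertical axis) by the length of their 5' overlap in nt (horizontal axis), in each heterozygote (blue) and mutant (red). Every library peaks at 10 nt, from 37.2% in the Yb mutant to 65.7% in the zuc mutant.

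Fragments of most structural RNAs were more abundant in the mutants per miRNA read. In the armi mutant 28S rRNA reads were 49.2 times, 18S rRNA reads 33.7 times and 5S rRNA reads 62.6 times the heterozygote. In Yb the ratios were 10.1, 8.27 and 19.6, in zuc 8.67, 10.7 and 4.21, and in CG4771 2.91, 2.81 and 1.46. Reads of the 2S rRNA that lacked its first bases were 104.8 times the heterozygote in armi and 37.1 times in Yb, against 14.2 times in zuc and 3.52 times in CG4771. Reads on tRNA-like contigs were 10.8 times the heterozygote in armi, 5.25 times in Yb, 13.2 times in zuc and 1.63 times in CG4771. All of these were called higher except 5S rRNA and tRNA-like reads in CG4771. All 2S rRNA reads together were 14.1 times the heterozygote in armi, 12.9 times in Yb and 4.03 times in zuc, but 0.551 of it in CG4771. Those that began at the first base of 2S rRNA stood at 1.77, 2.54 and 2.27 times the heterozygote in armi, Yb and zuc and at 0.359 in CG4771, none of them called. Per mapped read the armi value turned to 0.670, and all 2S rRNA reads in CG4771 stood at 0.986. U2 and U6 snRNA reads were higher in every mutant, from 3.77 times the heterozygote (U2 snRNA in CG4771) to 22.3 times (U6 snRNA in zuc).

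Among miRNAs, the ovary-enriched list had a median ratio of 0.600 in armi, 0.660 in CG4771, 0.939 in Yb and 0.560 in zuc, at percentiles 0.73, 2.93, 14.2 and 2.86 of matched random lists. Per mapped read the medians were 0.227, 1.18, 0.510 and 0.666 in the same order, so the direction in CG4771 turned, while a common factor leaves the percentiles unchanged. Of its 5 members, 2 were lower in armi, 1 in CG4771, 1 in Yb and 2 in zuc, and 1 was higher in zuc. In the armi mutant miR-994-5p stood at 0.112 and miR-318-3p at 0.243 of the heterozygote. In Yb miR-994-5p stood at 0.129, and miR-318-3p, at 0.479, stayed inside the range of the heterozygotes. In CG4771 miR-318-3p stood at 0.372. In zuc miR-989-3p stood at 0.454 and miR-184-3p at 0.449, whereas bantam-3p was 3.49 times the heterozygote. The zuc heterozygote was the lowest of the heterozygotes for bantam-3p, at 34962 RPM, counted over miRNA reads. The zuc mutant held 122064 and the CG4771 heterozygote 104096. The heterozygotes themselves ranged from 34701 to 141130 RPM, counted over miRNA reads, for miR-318-3p.

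The mir-309 cluster, known for its expression in the early embryo, was called higher in Yb and zuc and lay above the heterozygote in the other mutants at low counts. In Yb all 4 members with enough reads were higher, miR-286-3p at 349.2 times (95% interval 268.7 to 462.6), miR-3-3p at 303.8 times, miR-5-5p at 106.1 times and miR-6-3p at 89.0 times the heterozygote. In zuc all 3 were higher, miR-5-5p at 59.2 times, miR-286-3p at 44.2 times and miR-6-3p at 39.4 times. In armi and CG4771 0 members had enough reads to be called. At lower counts miR-286-3p went from 56 to 546 reads in armi, 24.2 times the heterozygote per miRNA read, and from 37 to 314 in CG4771, 7.24 times. There miR-6-3p stood at 9.40 times in armi and 3.07 times in CG4771, miR-5-5p at 12.6 and 5.33 times, and miR-3-3p at 28.1 and 3.05 times. In zuc miR-308-3p was 111.4 times its heterozygote, at 445.6 RPM, but the CG4771 heterozygote held 358.1.

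Other miRNAs also stood at the ends of the ranking. In armi miR-10-5p was 12.6 times, miR-252-5p 4.79 times, miR-34-5p 4.22 times and miR-316-5p 3.65 times the heterozygote, while miR-989-3p at 0.600 and miR-190-5p at 0.752 were not called. In CG4771 miR-1-3p, a muscle miRNA, was 2.42 times, miR-252-5p 2.40 times, miR-10-5p 2.15 times and miR-9a-5p 2.03 times the heterozygote. There miR-970-3p was lower at 0.493, and miR-92b-3p at 0.508 and miR-989-3p at 0.534 were not called. In Yb miR-79-3p was lower at 0.411, and miR-279-3p at 0.503 was not called. In zuc miR-263a-5p was lower at 0.383, and miR-318-3p at 0.560 was not called. Of 51 miRNAs with enough reads in armi 12 were higher and 2 lower, and of 53 in CG4771 4 were higher and 2 lower. Of 55 in Yb 15 were higher and 2 lower, and of 54 in zuc 10 were higher and 3 lower. Per mapped read, 6 of the 12 higher miRNAs of armi were below the heterozygote. The let-7 complex had 1 of 3 members higher in armi and 1 in Yb, with 0 in CG4771 and zuc. The mir-310 cluster had 1 of 4 higher in armi and 1 in Yb, with 0 in CG4771 and zuc. Per mapped read the median of the let-7 complex was 0.644 in armi and 0.812 in Yb, and that of the mir-310 cluster 0.526 and 0.760, below the heterozygote in each. In CG4771 they were 2.35 and 1.95, against 1.32 and 1.09 per miRNA read. Of 6 muscle and neuron miRNAs 4 had enough reads, of which 2 were higher in armi, 1 in CG4771, 1 in Yb and 0 in zuc. The median of these 4 was 2.77 per miRNA read and 1.05 per mapped read in armi, 2.72 and 1.48 in Yb, and 1.66 and 2.98 in CG4771. The muscle miRNA miR-133-3p had too few reads to be called. It went from 19 to 814 reads in armi, 106.3 times the heterozygote per miRNA read and 40.2 times per mapped read. Per miRNA read it stood at 14.4 times in Yb (20 to 137 reads), 9.31 times in zuc (24 to 261) and 3.32 times in CG4771 (35 to 136).

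**Figure D4:**
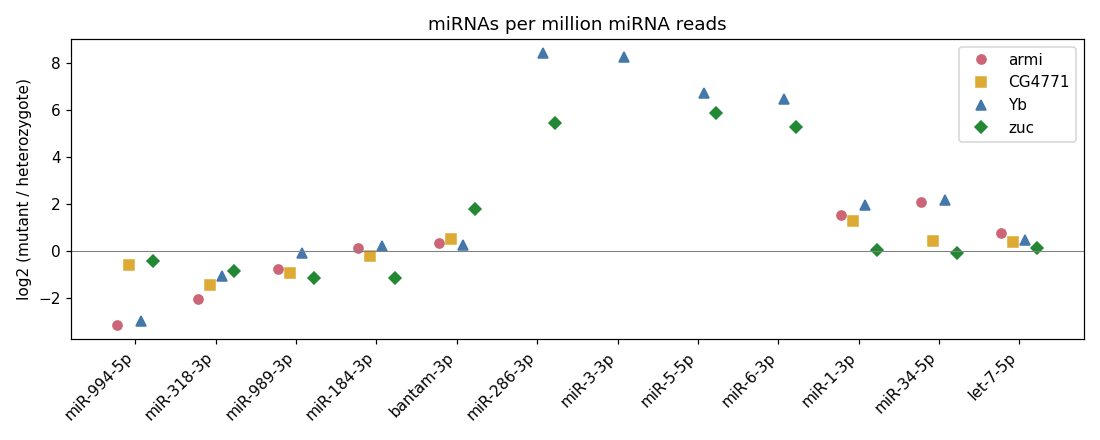
Log2 ratio of mutant to heterozygote in RPM, counted over miRNA reads (vertical axis) for 12 miRNAs of the fixed lists (horizontal axis), 1 symbol per comparison, drawn where at least 1000 reads were counted in either library. In Yb miR-286-3p lies highest, at 349.2 times the heterozygote, and in armi miR-994-5p lies lowest, at 0.112.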

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

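The tests of dilution, of cell content and of rRNA of every kind in this part were chosen only after the result had been seen, and that of truncated miRNAs before. Results were picked out here because the value in Yb had the opposite sign to those in the other mutants, or because reads outside the main measurement exceeded the highest heterozygote.

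The level of piRNA-length reads was 148.4% of the heterozygote in Yb, against 38.7% in armi, 22.4% in CG4771 and 21.4% in zuc. Dual-strand loci had a median of 163.0% in Yb, against 5.32%, 7.30% and 2.80% in the same order. The ping-pong share moved by -1.48 percentage points in Yb and by 14.4, 6.75 and 17.8 points in armi, CG4771 and zuc. No opposite change of the ping-pong share is shown. The intervals of Yb and CG4771 included 0, but they ignore that the 2 libraries of a pair share loci, so they do not settle the sign. These differences between genotypes were not tested, and the Yb directions of the level and of the dual-strand median depend on the normalizer.

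Reads of 18 to 22 nt outside the listed miRNAs, esi-2.1 and masked sequence came to 0.396 per miRNA read in the armi mutant, 0.498 in CG4771, 0.336 in Yb and 0.421 in zuc, all above the highest heterozygote at 0.331. The list is not complete, so these reads include any miRNA not on it. This depends on the normalizer. Of mapped reads they made up 3.91% in the armi mutant and 4.64% in Yb, below the highest heterozygote at 5.94%, and 15.99% in CG4771 and 10.9% in zuc, above it.

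In the Yb mutant, as in armi, the median uni-strand locus stood far below the median dual-strand locus. Dilution by rRNA and tRNA fragments is a single factor for all loci of a library, so it cannot make the gap of 1.84 on the log2 scale (95% interval over loci 1.57 to 2.07), which had been seen before this was weighed. It stays open for the levels per mapped read. A loss of the cells that make miR-318 and miR-994 stays open for Yb. There the uni-strand median fell by only 0.0775 more on the log2 scale than the less reduced of the pair (miR-318-3p), with different cell types not separated by these data. In zuc the uni-strand median fell by 5.23 more than the less reduced miRNA (miR-994-5p), which argues against such a loss as the whole cause there. This was not run as a test in armi. There the uni-strand median was 1.49% of the heterozygote, and the less reduced miRNA (miR-318-3p) stood at 0.243 of it.

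The armi and Yb mutants held many 2S rRNA reads without their first bases. Breakdown of all RNA predicts more miRNA reads that lack bases at the 5' end. The smaller of the armi and Yb ratios of that share was 0.310, and the armi ratio was 0.326, so the predicted rise was not seen. The share pools all listed miRNAs, and the abundant miR-994-5p stood at 0.112 of the heterozygote in armi and 0.129 in Yb. It was not split by miRNA, so a change in which miRNAs were present could also lower it. Breakdown therefore stays open. More rRNA of every kind is left open, since the lowest rise of 18S, 28S or 5S rRNA came to 0.223 of the rise of truncated 2S reads. No biological explanation was tested.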

How the results depend on the processing

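No paired analysis of a single gene was possible because each comparison was of 1 mutant and 1 heterozygous library. An effect shared by the mutants of all 4 genes, for which the 4 comparisons would serve as pairs, was not tested. All alternatives for uni-strand and dual-strand loci, esi-2.1 as normalizer, U-initial reads and the mask without its later addition were chosen after the data had been seen. Normalization to annotated hairpin endo-siRNA loci was not run. Of the settings tried, 34 left a value inside its interval, 39 moved it and 3 reversed the direction of a value whose interval lay on one side of no change. Beyond these, the ping-pong difference changed sign in CG4771 (genome-unique reads) and in Yb (0.283 points, each distinct sequence counted once), where the interval of the main value included 0. The cause was not tested unless stated. Values below are percent of the heterozygote in the order armi, CG4771, Yb, zuc. The piRNA-length level was 14.6, 40.02, 80.6 and 25.5 per mapped read, where Yb reversed. It was 17.9, 16.2, 52.1 and 14.8 per esi-2.1 read, where Yb reversed again. It was 35.7, 20.5, 147.3 and 19.5 for 24 to 28 nt, 40.8, 19.5, 154.6 and 19.9 for genome-unique reads, 33.8, 17.1, 150.4 and 19.3 for U-initial reads, and 77.9, 23.5, 153.9 and 25.6 without the added mask. The armi value without that mask came from reads on contigs carrying rRNA or snRNA motifs, and its size shows how far incomplete masking can move a total. Per mapped read, uni-strand medians were 0.562, 9.39, 24.7 and 2.36, and dual-strand medians 2.01, 13.1, 88.6 and 3.34, where Yb reversed. With 200 nt tiles, uni-strand medians were 2.09 in armi and 57.2 in Yb, and the dual-strand median was 6.36 in armi. With U-initial reads, the uni-strand median was 4.86 in CG4771, and dual-strand medians were 6.37 in CG4771 and 170.9 in Yb. For 24 to 28 nt the dual-strand median was 2.48 in zuc. The ping-pong difference was -5.30 points in CG4771 and 34.9 in zuc with genome-unique reads, and 4.83 in zuc with each distinct sequence counted once. The lower levels in armi, CG4771 and zuc kept their direction under every setting tried. Counting intervals at these depths are far narrower than the spread among heterozygotes, so depth does not limit the totals.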

Other observations

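The test of degradation in this part was chosen after related values had been seen, and the others before their results. Reads of 21 nt outside masked sequence and the incomplete list of miRNAs came to 256932 RPM, counted over miRNA reads, in the zuc mutant and 78127 in its heterozygote. The corresponding values were 227529 and 66975 in armi, 246343 and 139508 in CG4771 and 152065 and 78385 in Yb. Per mapped read these ratios were 3.91 in zuc, 1.28 in armi, 3.16 in CG4771 and 1.05 in Yb, so the Yb rise rests on the normalizer and most of the armi rise does too. The endo-siRNA esi-2.1 stood at 12372 RPM in the armi mutant, 10787 in Yb, 10327 in zuc and 4342 in CG4771, against 3149 to 7135 in the heterozygotes. Per mapped read it was 0.817 of the heterozygote in armi, where the direction turned, and 1.55 times it in Yb, 1.72 times in zuc and 2.47 times in CG4771. On that scale only zuc, at 0.267% of mapped reads, lay outside the range of the heterozygotes, 0.0565% to 0.155%.

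Across the 783 dual-strand loci, the log2 ratios of armi, CG4771 and zuc rose and fell together. Spearman's rho was 0.73 for armi with zuc (95% interval from resampling loci 0.69 to 0.77), 0.71 for CG4771 with zuc and 0.69 for armi with CG4771. With Yb it was -0.07 for armi, -0.17 for CG4771 and -0.22 for zuc. Each mutant had its own heterozygote, so these values share no controls, but they are across loci, which are not independent replicates.

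Dual-strand loci kept very different shares of their piRNAs in zuc. The hypothesis that loci with more ping-pong in the heterozygote kept more required a rho of 0.3 or more. Its rho was 0.0824 (95% interval 0.0116 to 0.154). The interval lies wholly below 0.3, which argues against a link of that size over these loci. A weaker link is not excluded, since the upper bound exceeded the limit set for that. Degradation fragments would lower the share of reads beginning with U at the 196 loci that kept most. That share, over the pooled reads of these loci, fell by only 3.12 percentage points, from 77.1% to 74.0%. This argues against such fragments as most of the pooled reads. Abundant loci weigh most in the pool, so fragments at less abundant loci are not excluded. Copy number in the genome had a rho of 0.31 (95% interval 0.24 to 0.38) with the ratio, and the interval reached below the 0.3 set in advance, so this stays open.

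piRNAs that follow head to tail on 1 strand were tested with the hypothesis that Zuc makes the 3' end that sets the next 5' end. Among distances of 1 to 20 nt from a 3' end to the next 5' end, the share at 1 nt was 12.1% in the zuc heterozygote and 4.20% in the mutant, or 34.9% of it. Every heterozygote was above 10%, as the hypothesis required. The share was 2.36% in the armi mutant against 13.2%, 7.74% in CG4771 against 11.4% and 12.04% in Yb against 13.5%. The share of U at the first base after the 3' end exceeded the next 10 bases by 21.3 points in the zuc heterozygote and 2.60 in the mutant, or 12.2% of it. The excess was 0.482 points in the armi mutant, 16.9 in CG4771 and 18.2 in Yb. Both tests are consistent with Zuc making these ends, but armi gave lower values, so the tests do not single out Zuc.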
